A study of Mus musculus with 32 samples.

How the data were processed

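The series holds 32 libraries of mouse hippocampus, 16 captured with the ac4C antibody and 16 inputs. Per the labels' protocols, total RNA was extracted with Trizol, fragmented to about 200 nt, captured with the antibody on protein A/G beads of an ac4C RIP kit and made into libraries with a whole RNA kit for low input. Per the submitters' processing notes, the tools included FastQC, cutadapt 1.9.3 and HISAT2 2.0.4, with the mm10 build. The peak caller and its settings are not given in the sources used here. Each of the 16 captured libraries has its own deposited peak list, so peaks were called per sample, and the inputs have no list of their own used here.

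Per the file headers, the authors gave each peak a score, a fold enrichment, a -log10 p-value and a -log10 q-value, together with the name of a gene. The deposited fold is above 2 and the deposited -log10 q-value above 1.3 in every list, as tested on the files. By the gene type that the files give, the lists name protein-coding genes, apart from 1 row of the first control list. They hold no mitochondrial chromosome. So 2 of the 21 gene lists fixed beforehand, nucleus-retained long noncoding RNAs and mitochondrial genome transcripts, could not be tested. The files give no read counts and the depth per sample is unknown. Intervals on shares cover counting error only. An ac4C peak that is missing from a list may have been present under the authors' threshold.

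The deposited lists use gene symbols of different ages. Of 13302 names, 12937 were current symbols of the RefSeq table of GRCm38.p6, which is the mm10 assembly, 214 were updated through a synonym of 1 gene only and 151 were kept, which left 13143 genes. Updated names numbered 53 to 119 per homogenate list and 0 to 6 per synapse, control or cKO list. Unmatched names numbered 4 to 126 per homogenate list and 0 in each other list. Peaks were called inside a gene when they overlapped the span of the named gene in that table, which held for 72.4% to 90.3% of peaks per list. The L list of the synapse on day 6 ends at position 118984776 of chromosome 7 in file order, and 14.9% to 15.8% of the peaks of the other synapse lists lie beyond it. It has 6827 rows, as does the C list of day 1. Values for that list were given as deposited and within the range it reaches. The peak names inside the first homogenate L list carry the number 2, and the list was kept under the number of its label.

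Lists were compared by the presence or absence of peaks and not by the size of the fold, though an alternative kept only peaks with a fold of at least 5. Numbers of peaks and genes were compared with exact two-sided permutation tests of the difference in means, over 20 assignments for 3 against 3 lists, 6 for 2 against 2 and 28 for 6 against 2. Synapse and homogenate lists of all days were compared over 924 assignments of single lists and, as an alternative chosen later, with C and L lists of 1 number or day as 1 unit. C and L over both fractions were compared with a stratified exact test over 160 assignments. Genes with a peak in every list of 1 group and none of the other were counted and set against all other splits of the same lists. The share of each gene list's members with a peak, among members with a peak in any list, was tested in the same way with Benjamini-Hochberg adjustment over 19 lists. For 1 list against 1, no test was made, and a list's net gain was set against 10000 random lists. A result passed at an adjusted p under 0.05.

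The genes named were chosen by a rule fixed before the data were examined. It took the 10 genes per direction with the highest mean percentile of the authors' fold within the lists that hold them, 5 per synapse day and direction, and up to 4 members per gene list. Predicted symbols were skipped, and some genes that the rule takes are not reported here. The gene lists, tests and alternatives were also fixed before the data were examined, apart from those said to be chosen later.

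Whether replicate numbers pair the homogenate samples was checked from the deviations of gene presence from the group means. Lists of the same number correlated at 0.314, 0.221 and 0.116 over 12908 genes, and each over 0.1, so the numbers were taken to pair the samples. This pairing comes from the data, as the labels give only the numbers. The first C and L lists also differed in form from the other homogenate lists. They held 108 and 126 names that stayed unmatched, against 4 to 6, and only in them did no peaks join at 500 bp. Shared processing of lists of 1 number thus cannot be told apart from a pairing of the samples.

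The counts were tested on simulated lists drawn from the homogenate presence rates of 12908 genes, each list apart, with no pairing by number. Of 200 genes made to be present in L alone, all 200 were recovered and 63 unchanged genes were called. With a chance of presence of 90% in L and 10% in C, 108 were recovered, or 54%, and 70 unchanged genes were called. With no changed gene, 51 genes still had a peak in every L list and no C list, a value that leaves out the pairing. With the pairing kept, 255 genes differed within all 3 same-numbered homogenate pairs, of which 31.9 would be in L alone and 31.9 in C alone if the direction within a pair were random. Alternatives covered stricter thresholds, merged peaks, covered bases, overlap of peaks in place of genes, equal numbers of top-ranked peaks, replicate blocks and leaving out each list. Regions of transcripts and the sequence context of peaks were not analysed here, for want of exon annotation and a genome sequence. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.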

Results

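N4-acetylcytidine (ac4C) is an acetylated form of cytidine in RNA, and the series followed it in mouse hippocampus during learning and memory. RNA fragments of about 200 nt were captured with an antibody against ac4C and sequenced beside the unselected input, an assay called acRIP-seq. The 16 peak lists analysed here each came from 1 captured library. The homogenate of the tissue gave 3 lists of group C and 3 of group L on day 6. The synapse fraction gave 1 list of each group on days 1, 6 and 20. A separate set held 2 control lists and 2 lists of a conditional knockout, written cKO. The peak names inside the files read Control for C and Learning for L. The labels do not say that samples came from separate animals, so the p-values measure only the spread between these samples, which may be technical. The lists hold no read counts, so the depth is unknown. All positions are of the mm10 build. Every fold enrichment quoted is the authors' value of that peak and ranks peaks within its own list only. Where a highest fold over several lists is given, it only picks an example peak. No exon annotation was used here, so a peak's place is given as inside or outside the span of its named gene.

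**Figure D1:**
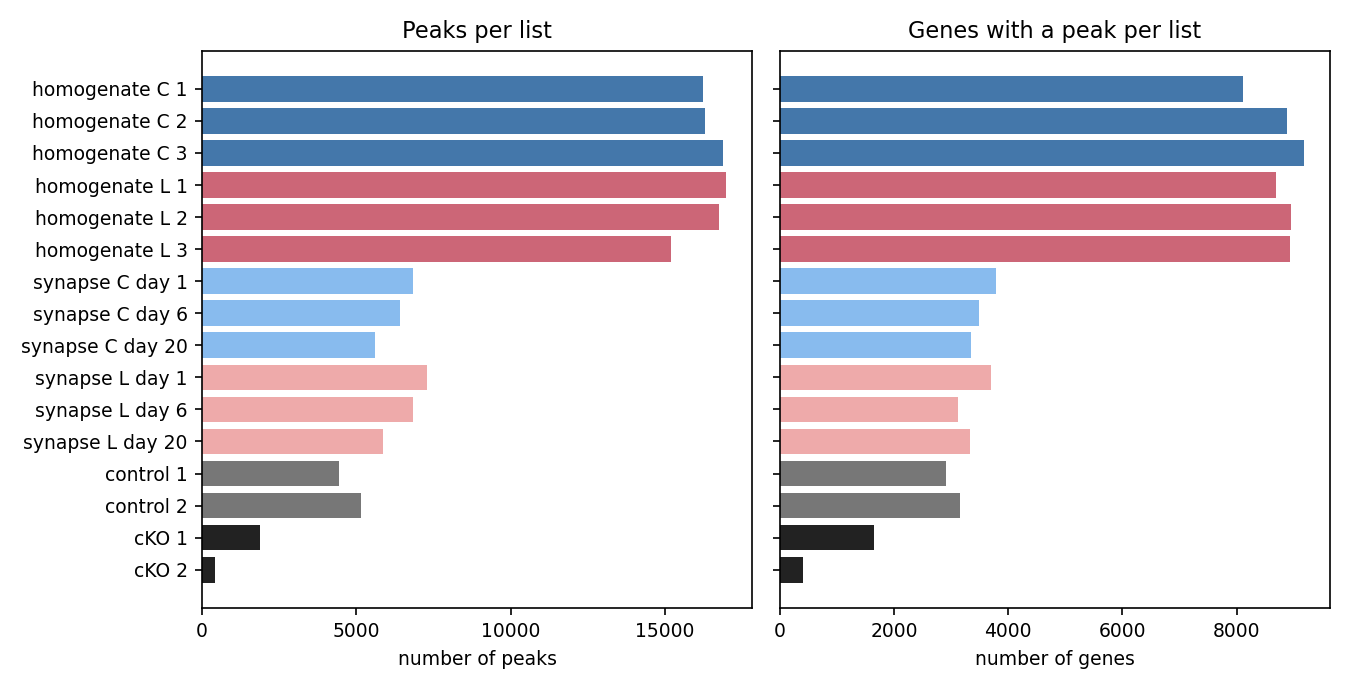
Number of peaks (left axis panel) and of genes with at least 1 peak (right axis panel) in each of the 16 lists, 1 bar per list. The 6 homogenate lists hold 15182 to 16971 peaks, the 6 synapse lists 5586 to 7293, the control lists 4446 and 5132 and the cKO lists 1887 and 422.

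The homogenate comparison asked which transcripts carried ac4C peaks in group L and not in group C on day 6. Lrrc4c, a postsynaptic adhesion protein, Snn and Trnau1ap, which binds the selenocysteine tRNA, had a peak in all 3 L lists and in no C list. B4galt2, a galactosyltransferase, Emc8, the RNA-binding protein gene Rbm47, Best3, Clec2d, the kinase gene Riok1 and Pld5 followed by the fixed ranking, and 35 genes had this pattern in all. Ifitm3, an interferon-induced membrane protein, Ttc39c, Fbn1, which encodes fibrillin-1, and Nudt1, which clears oxidised nucleotides, had a peak in all 3 C lists and in no L list. Tmem175, a lysosomal potassium channel, Mrgbp, Helb, Cdca7, Klhdc8a and the nuclear import receptor Tnpo1 were the next of 27 such genes. The Lrrc4c peak with the highest fold, 45.4, lay inside the gene at chromosome 2, 97466409 to 97467493, in the second L list. The Ifitm3 peak with the highest fold, 52.2, lay inside the gene at chromosome 7, 141010273 to 141010794, in the second C list. Lrrc4c and Snn also had peaks in synapse lists of both groups, so neither is a gene of L lists alone over the whole series.

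The groups did not differ in size by more than the spread between lists. The C lists held 16467 ± 354 peaks (SD, n = 3) and the L lists 16298 ± 973 (SD, n = 3; exact two-sided permutation p = 0.9). Genes with a peak numbered 8722 ± 551 in C and 8860 ± 146 in L (SD, n = 3 each; exact two-sided permutation p = 0.8), and 3 against 3 lists cannot give a p under 0.10. The mean Jaccard index of the gene sets, the shared genes over all genes of a pair, was 0.638 within groups and 0.661 between them. The lists that share a number across groups, at a mean of 0.708, made this gap, and without these pairs the index between groups was 0.638 as well. The 35 and 27 genes together made 62, and the other 9 of the 10 ways to split the 6 lists gave 50 to 264. Each of the 6 omissions of 1 list raised both counts by over 1.5 times, to 78 to 153 genes of L alone and 51 to 128 of C alone, since fewer lists then had to meet the condition. Of the 19 gene lists tested, 11 had a higher mean share of members with a peak in L and 8 a lower one, and the smallest exact two-sided permutation p was 0.3, 1 after Benjamini-Hochberg adjustment. The widest gaps were in translation factors, at 60.2% ± 10.4 in C and 73.1% ± 9.31 in L, and in chromatin and histone acetylation genes, at 82.8% ± 6.31 and 74.7% ± 4.63 (SD, n = 3 each). Eif5b, Eif3b, Fmr1 and Eif3d of the first list and Chd3, Arid1b and Ep300 of the second had a peak in all 6 homogenate lists.

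The synapse comparison set L against C on each day with 1 list per group, so no difference here has a replicate check. Palm, which encodes the membrane-shaping protein paralemmin, Slc38a10, Rhbdd1, Plod1, a collagen lysyl hydroxylase, and Tcf7l2, a transcription factor of Wnt signalling, had a peak in L at all 3 days and in C at none. Nudt4, Tmbim6, the extracellular glutathione peroxidase gene Gpx3, Plxnb2 and Lims1 completed the first 10 of 30 such genes. Ppa2, the mitochondrial pyrophosphatase, Rps6kb1, which encodes the ribosomal protein S6 kinase, the initiation factor gene Eif2a and Fgf11 had a peak in C at all 3 days and in L at none. Rgs12, Mgat2, Ufm1, the potassium channel subunit gene Kcnmb4 and Mkln1 were others of 28 such genes. The Palm peak with the highest fold in L, 36.3 on day 1, lay inside the gene at chromosome 10, 79793591 to 79793846. These sets use the part of the genome that the shortest-reaching list covers, since the L list of day 6 ends within chromosome 7 in file order and holds no peak beyond it. The other 9 splits of the 6 synapse lists gave 40 to 123 genes in both directions together, against 58 for C and L. The 3 of these that also part the lists of each day gave 40, 58 and 66.

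By day, Palm, R3hdm2, Snx32, the proton-pumping transhydrogenase gene Nnt and Igf1 led the genes of L alone on day 1, and Zfp800, Man2a1, the deubiquitinase gene Usp1, Cds1 and Appbp2 those of C alone. On day 6, Aldh2, the mitochondrial aldehyde dehydrogenase, the phosphodiesterase gene Pde10a, Sfr1, Sp2 and Rapgef6 led in L, and Dgkz, a diacylglycerol kinase, Ddah1, the DNA demethylation enzyme gene Tet2, Cadm2 and Acsl3 in C. On day 20, Snx32, Zfp91, Rps26, Slc38a10 and Stk38 led in L, and Gprin3, Erp44, Mrpl17, Lsm14b and Grpel1 in C. On day 1, 823 genes had a peak in L alone and 897 in C alone, with 2884 shared. On day 20 the counts were 977, 1003 and 2351. On day 6 they were 872, 1238 and 2254 as deposited, and 872, 663 and 2254 within the range both lists reach. The L lists held 1.07, 1.06 and 1.05 times as many peaks as the C lists on days 1, 6 and 20, and 0.98, 0.895 and 0.992 times as many genes. Within the range both lists reach, day 6 gave 1.26 times as many peaks and 1.07 times as many genes in L, which turns the direction for genes. Among peaks with the authors' -log10 p of at least 10, L held 0.932 times as many as C on day 1, and among those with a fold of at least 5 it held 1.03 times as many genes on day 1 and 1.02 times as many on day 20, which turns these directions. The median L peak was shorter on each day, 197 bp against 381 bp on day 1, 188 bp against 278 bp on day 6 and 229 bp against 289.5 bp on day 20. The L peaks covered 0.536, 0.713 and 0.815 times as many bases, with 0.842 on day 6 within the range both lists reach, so the direction depended on whether peaks or bases were counted.

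Gene lists were set against 10000 random lists matched in size and in how many other libraries had a peak, in the range every list reaches. Postsynaptic density and glutamate receptor genes gained 3 members and lost 2 from C to L on day 1, at percentile 74.55, gained 8 and lost 2 on day 6, the 98.1st percentile, and gained 8 and lost 1 on day 20, the 99.5th percentile. Dlgap3 and Grin2a, a scaffold protein and an NMDA receptor subunit of that list, had a peak in all 6 synapse lists. Genes of calcium, cAMP and MAPK signalling of long-term potentiation gained 3 members and lost 14 on day 20, the 0.05th percentile, after gaining 5 and losing 1 on day 1, the 94.3rd, and gaining 8 and losing 2 on day 6, the 94.7th. Gnaq and Prkar1a of that list had a peak in all 6 synapse lists. Endothelial and mural cell markers gained 4 members and lost none on day 6, the 99.2nd percentile, against 1 and none on day 1, the 80.3rd, and 1 and 1 on day 20, the 48.5th. Nuclear genes of the mitochondrial respiratory chain gained 12 and lost 6 on day 1, at percentile 97.53, against 10 and 7 on day 6, the 61.9th, and 7 and 8 on day 20, the 43.8th. Activity-induced immediate early genes had a peak for 69.6%, 56.5% and 60.9% of 23 members in C and 56.5%, 47.8% and 43.5% in L on days 1, 6 and 20, with percentiles of 9.43, 13.7 and 4.72. Nr4a3, Jun, Homer1 and Egr3 of that list had a peak in all 6 synapse lists. Of 57 such percentiles, 5 lay outside the central 95%, where 2.85 would by chance alone.

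Over homogenate and synapse together, the number of genes with a peak differed between L and C by a mean of -0.02 on the log2 scale (exact two-sided stratified permutation p = 0.55, where 0.013 is the smallest that the 160 assignments allow). Within the range every list reaches, the difference was 0.02 with p = 0.475 in the same exact permutation test. Translation factors had a peak for 52.7% ± 11.3 of members in C and 60.8% ± 14.9 in L (SD over 6 lists each; exact permutation p = 0.075, adjusted p = 0.831). Chromatin and histone acetylation genes stood at 57.1% ± 28.5 and 50.5% ± 27.0 (exact stratified permutation p = 0.0875, adjusted p = 0.831). The SDs in this paragraph span both fractions, while its p-values come from the stratified test, which exchanges C and L only within homogenate or within a synapse day. Immediate early genes stood at 74.0% ± 16.3 and 66.7% ± 22.4 (exact permutation p = 0.15, adjusted p = 0.95). Endothelial and mural cell markers stood at 22.5% ± 20.9 and 29.4% ± 18.6 (exact permutation p = 0.25, adjusted p = 0.95). None of the 19 lists had an unadjusted p under 0.05 in the lists as deposited. Within the range every list reaches only translation factors did, at 52% ± 11.3 in C and 64.7% ± 15.1 in L (SD over 6 lists each; exact permutation p = 0.025, adjusted p = 0.475).

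The cKO comparison asked which ac4C peaks were present in control tissue and missing in the knockout. The labels do not name the deleted gene. Nat10, which encodes the known ac4C writer, had no peak in any list of this set, controls included, so its peaks check nothing about the knockout. Agap2, a GTPase-activating protein, Ube2e2, the dynein light chain gene Dynll1, Ndrg3 and Snap91, a clathrin assembly protein of synaptic vesicles, had a peak in both control lists and in neither cKO list. R3hdm4, Map7d2, Tmed2, a protein of secretory transport, Ubqln1 and Tpd52 completed the first 10 of 1414 such genes, out of 2302 with a peak in both controls. The reverse held for 42 genes, led by Mal2, Tpd52l2, Gria3, which encodes an AMPA receptor subunit, Zfp367 and Galc, the lysosomal galactosylceramidase. Sh3bgrl2, Rcan1, a calcineurin inhibitor, Cwf19l2, Aig1 and the phagocytic receptor gene Mertk followed. The Agap2 peak with the highest fold in the controls, 38.3, lay inside the gene at chromosome 10, 127078869 to 127079320, and the Gria3 peak with the highest fold in cKO, 27.7, inside the gene at chromosome X, 41401209 to 41401430. At 282 genes all 4 lists held a peak, which need not lie at the same place. The other 2 splits of the 4 lists gave 151 and 179 genes in both directions together, against 1456 for control and cKO. Both other splits put a cKO list, of 1643 or 414 genes, in each group, which limits the genes that a group can share. This contrast thus cannot be told apart from the shorter cKO lists.

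The control lists held 4789 ± 485 peaks and the cKO lists 1155 ± 1036 (SD, n = 2 each), a ratio of means of 0.241 (exact two-sided permutation p = 0.333, the smallest that 2 against 2 lists allow). The ratio was 0.424 in the first pair and 0.0822 in the second. Of the genes with a peak in the first control list, 35.5% had one in the first cKO list (95% Wilson interval 33.8 to 37.2). In the second pair the share was 10.7% (95% Wilson interval 9.68 to 11.8). By position, fewer peaks were kept. In the first pair 589 of 4446 control peaks, or 13.2%, were overlapped by a cKO peak, and in the second 277 of 5132, or 5.40%. A gene that kept a peak thus did not always keep it at the same place. The shares of all 19 gene lists were lower in cKO, each without passing the test. All genes with a peak in any list stood at 22.2% and 24.1% in the control lists and 12.5% and 3.15% in the cKO lists. A lower share in cKO thus does not set a gene list apart from genes in general. Postsynaptic density and glutamate receptor genes stood at 69.0% ± 3.37 in control and 15.5% ± 8.42 in cKO, with Dlgap4, Dlgap3 and Grin2a in both controls and neither cKO list. Cytoskeleton and axonal transport genes stood at 77.9% ± 2.08 and 13.2% ± 6.24, with Kif5a and Map1a in both controls and neither cKO list. RNA modification enzymes and readers stood at 29.6% ± 5.24 and 14.8% ± 5.24 (SD, n = 2 each), with Zc3h13 and Adarb1 in all 4 lists. Among the 24 cytoskeleton and axonal transport genes in both controls, 18 were in neither cKO list, the 96.0th percentile of matched random lists. Among 22 genes of calcium, cAMP and MAPK signalling, 10 were in neither, the 4.74th percentile, and Gnaq and Camkk1 were in all 4 lists. These are the highest and lowest of 18 such percentiles, of which 0 lay outside the central 95%. For the net change from control to cKO within each pair, 8 of 38 percentiles did, where 1.9 would by chance alone. All were low. Cytosolic ribosomal proteins (0.01 and 0.08), nuclear respiratory chain genes (0.015 and 0.03) and cytoskeleton genes (0 and 1.77) were outside in both pairs. Postsynaptic genes (0.275) and endothelial and mural cell markers (2.03) were outside in the first pair alone. Among members in both controls, absence from both cKO lists stood at the 93.1st percentile for ribosomal and the 52.3rd for respiratory chain genes. The first control and cKO lists share a minimum peak length of 150 bp, while the second pair has 200 bp in control and 500 bp in cKO. Of the 5132 peaks of the second control list, 881 were at least 500 bp long, against 422 peaks in its cKO list. With the 422 top-ranked peaks of each list, 129 genes were in both controls alone and 170 in both cKO lists alone, a setting that keeps all of the second cKO list and only the top of each control list. Without the second cKO list, 400 genes were in cKO alone in place of 42, and without the first or second control list 64 or 73.

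**Figure D2:**
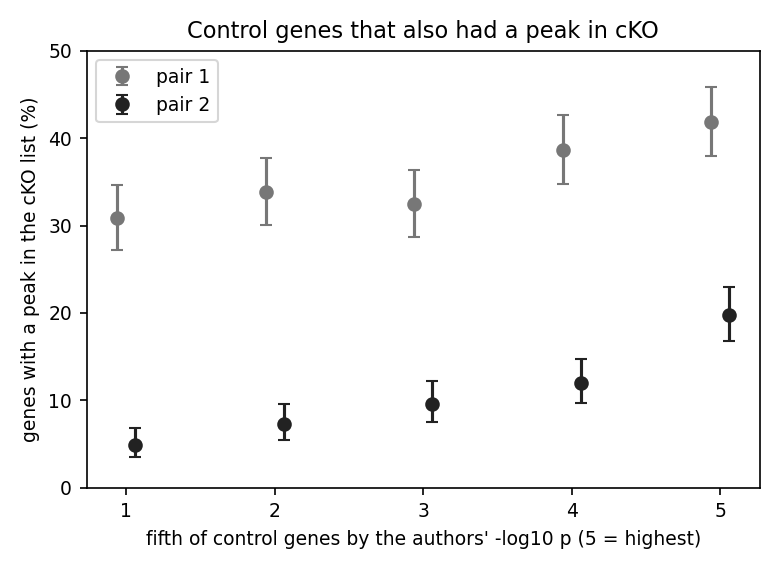
Share of genes with a peak in a control list that also had a peak in the cKO list of the same number (vertical axis, percent), by quintile of the control genes ordered by the authors' -log10 p (horizontal axis, 5 highest). Bars are 95% Wilson intervals, and the share ran from 30.8% in the lowest to 41.9% in the highest quintile in pair 1 and from 4.9% to 19.7% in pair 2.

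Day 6 allowed the synapse fraction to be set against homogenate. Tmem38b, a cation channel of the endoplasmic reticulum, Znhit6, Auts2, the vesicle trafficking gene Nbea and Nufip2 had a peak in all 6 homogenate lists and in neither synapse list of day 6. The histone genes H2ac4 and H2ac7, Cracd, Rrbp1 and the spectrin gene Sptbn4 completed the first 10 of 1820 such genes in the range every list reaches, or 2219 in the lists as deposited. The splicing factor genes Sfpq and Sf3b1, Ly6h, Stard3nl and Igf1 led the 21 genes with a peak in both synapse lists of day 6 and in no homogenate list. Pigg, Evi2a, the kinase gene Abl2, Ache, which encodes acetylcholinesterase, and Sspn followed. The H2ac4 peak with the highest fold, 287, lay inside the gene at chromosome 13, 23750979 to 23751645, in the second L list of the homogenate. The Sfpq peak with the highest fold, 94.6, lay inside the gene at chromosome 4, 127021506 to 127022360, in the L synapse list of day 6.

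The synapse lists held 3309 ± 259 genes (SD, n = 2) and the homogenate lists 8791 ± 368 (SD, n = 6), a ratio of 0.376 (exact two-sided permutation p = 0.0714, the smallest that 6 against 2 lists allow). Within the range every list reaches they held 3021.5 ± 148 and 7383 ± 314 genes. With the synapse lists of all 3 days the ratio was 0.394 (exact permutation p = 0.00216, the smallest that 6 against 6 lists allow when all 12 are taken as independent). With the C and L lists of 1 replicate number or 1 day taken as 1 unit, 3 against 3 units gave an exact permutation p of 0.10, the smallest they allow, which cannot pass the threshold. With equal numbers of top-ranked peaks, 640 genes were in all homogenate lists alone and 263 in both synapse lists alone. The 21 synapse genes became 36 or 45 without homogenate L list 1 or 3 and 71 or 68 without the C or L synapse list. Homogenate and synapse lists also differed in the age of their gene symbols. A difference in gene annotation was thus not tested apart from a difference between the fractions.

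On day 6, all genes with a peak in any list stood at 66.9% ± 2.80 in homogenate and 25.2% ± 1.97 in synapse, and histone genes had a peak for 72.5% ± 7.53 of members in homogenate and 0.694% ± 0.982 in synapse. Choroid plexus markers such as Clic6 and Kcnj13 stood at 61.5% ± 11.9 and 3.85% ± 5.44, RNA modification enzymes and readers at 78.4% ± 7.91 and 24.1% ± 7.86, and chromatin and histone acetylation genes at 78.8% ± 6.64 and 27.3% ± 8.57. Endothelial and mural cell markers such as Flt1 and Myl9 stood at 43.1% ± 6.08 and 11.8% ± 16.6, and nuclear genes of the mitochondrial respiratory chain at 63.7% ± 8.48 and 27.4% ± 1.68. Immediate early genes stood at 87.3% ± 4.68 and 48.0% ± 5.66, hippocampal principal neuron markers at 81.2% ± 7.61 and 47.8% ± 6.15, and oligodendrocyte lineage markers at 81.7% ± 6.06 and 50% ± 7.07. Calcium, cAMP and MAPK signalling genes stood at 83.3% ± 3.01 and 57.0% ± 4.24, translation factors at 66.7% ± 11.3 and 46.8% ± 2.28, and cytosolic ribosomal proteins at 56.8% ± 12.4 and 43.2% ± 3.60. Postsynaptic genes stood at 79.8% ± 5.78 and 66.7% ± 0, presynaptic vesicle cycle genes at 81.0% ± 9.85 and 69.4% ± 7.86, voltage-gated ion channels at 86.0% ± 4.33 and 74.3% ± 1.91, and cytoskeleton and axonal transport genes at 84.8% ± 10.1 and 73.5% ± 0. GABAergic genes stood at 66.0% ± 9.03 and 56.0% ± 5.66, microglia and macrophage markers at 50% ± 18.5 and 47.1% ± 0, and astrocyte markers at 87.5% ± 7.58 and 87.5% ± 3.54 (SD; n = 6 homogenate and 2 synapse lists throughout). These values are as deposited, where the L synapse list of day 6 lacks part of the genome. Each share is among members with a peak in any list, which were 72 of 103 histone genes and 13 of 15 choroid plexus markers. Over all members these shares would be lower. Within the range every list reaches, postsynaptic genes stood at 80.8% ± 4.95 and 75.8% ± 12.9. Ion channels stood there at 84.3% ± 4.85 and 80.3% ± 6.43, and 18 of the 19 lists were lower in synapse and 1 higher. As deposited, the smallest adjusted p over the 19 lists was 0.113 in the exact permutation test of day 6, which could not reach 0.05 for a single list. With the synapse lists of all 3 days and every list taken as independent, 15 of the 19 lists were lower in synapse at an adjusted p under 0.05 in the exact permutation test, and presynaptic, cytoskeleton, astrocyte and microglia genes were not (adjusted p = 0.144, 0.0668, 0.0943 and 0.703). All genes stood at 66.9% ± 2.80 and 26.4% ± 1.88 in these lists (SD, n = 6 each), so passing this test does not set a gene list apart from genes in general. Of the 15, only histone, choroid plexus, chromatin and RNA modification genes lay further below homogenate in percentage points than all genes did, and as a ratio endothelial and mural cell markers did in place of RNA modification genes, a comparison made after the data were seen and not tested. Within the range every list reaches the number was 13, as postsynaptic genes and voltage-gated ion channels no longer passed (exact permutation adjusted p = 0.123 and 0.0705). With pairs of C and L lists as units, 0 of the 19 lists passed or could pass (smallest exact permutation adjusted p = 0.146).

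The synapse lists were shorter, so the shares were also taken over the 4717 top-ranked peaks of each list in the range every list reaches, with the synapse lists of all 3 days. This setting was chosen after the data were seen. It keeps most of each synapse list and only the top of each homogenate list, so a higher share in synapse does not by itself show a gain. A lower share in synapse is not due to shorter lists here, but has to be read against all genes, which were lower too. Taking every list as independent, 5 gene lists were lower in synapse at an adjusted p under 0.05 in the exact permutation test and 2 were higher, voltage-gated ion channels and microglia and macrophage markers, and with pairs as units none could pass. Histone genes stood at 56.1% ± 6.99 in homogenate and 0.735% ± 0.805 in synapse, choroid plexus markers at 25.0% ± 13.9 and 2.78% ± 4.30, and chromatin and histone acetylation genes at 52.7% ± 9.27 and 26.7% ± 4.13. RNA modification enzymes and readers stood at 47.7% ± 3.8 and 30.3% ± 8.94 (SD, n = 6 lists each). All genes stood at 30.8% ± 2.01 and 24.6% ± 1.11 in this setting, and were, like these 4 lists, lower in each of the 6 synapse lists than in any homogenate list. Against this fall, voltage-gated ion channels stood at 54.0% ± 5.88 and 71.7% ± 3.67, and microglia and macrophage markers at 16.7% ± 3.65 and 41.1% ± 6.55. As deposited, both lists were lower in synapse. Their difference from genes in general was not tested. Kcnc1 and Cacna1e of the voltage-gated ion channels and Selplg of the microglia markers had a peak in every homogenate and synapse list as deposited.

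**Figure D3:**
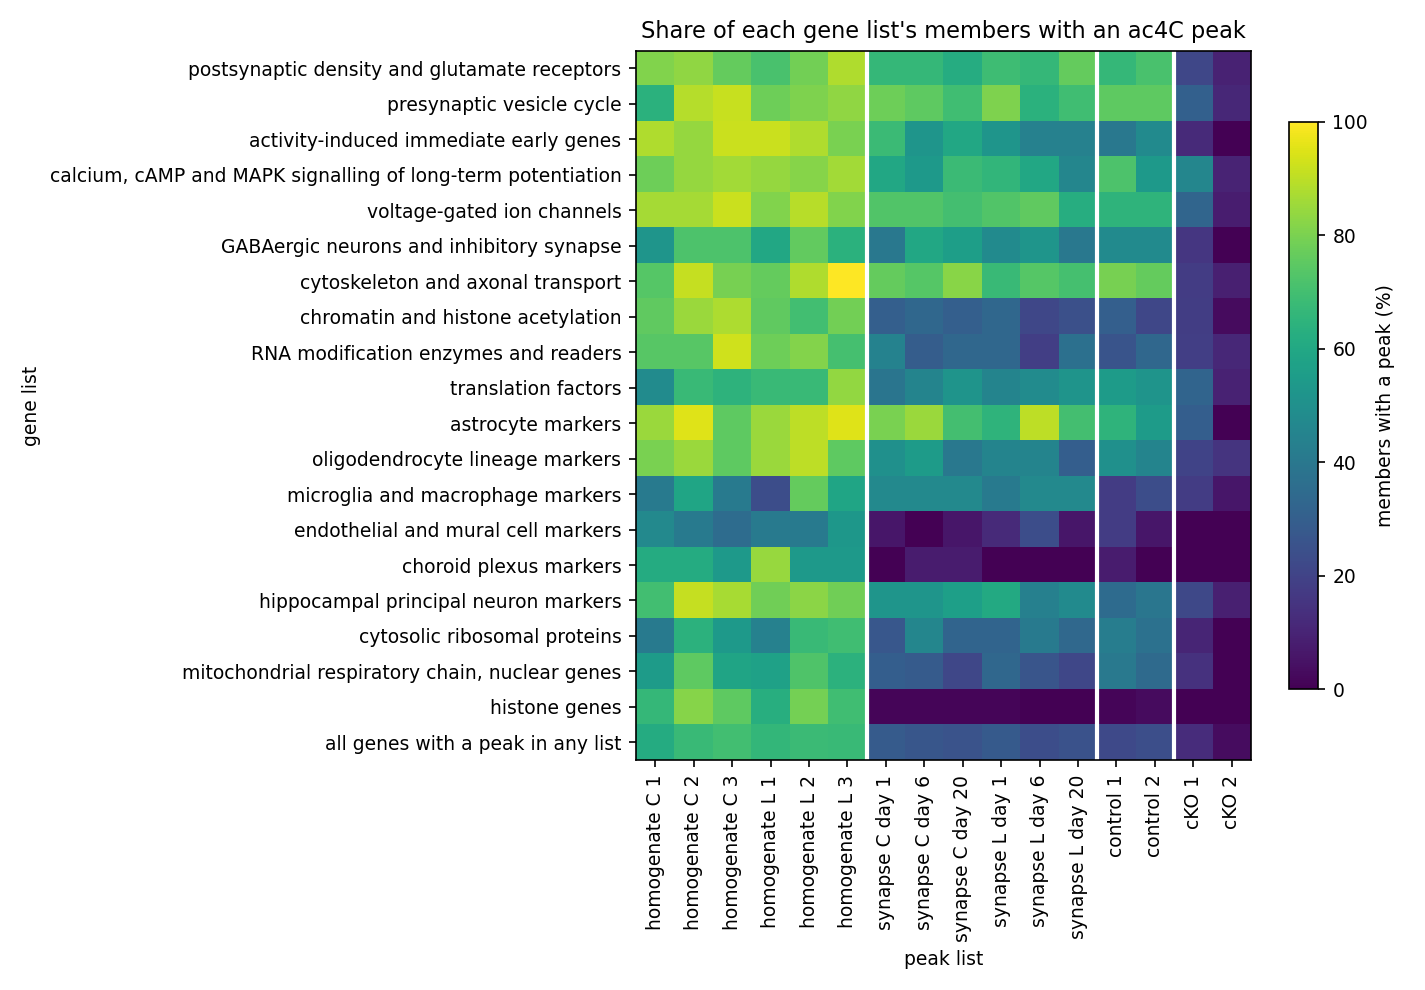
Share of each gene list's members with a peak (colour scale, percent) by gene list (vertical axis) and peak list (horizontal axis), with white lines between homogenate, synapse, control and cKO lists. Shares are among members with a peak in any list. Histone genes range from 62.5% to 81.9% over the homogenate lists and from 0% to 1.39% over the synapse lists.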

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

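The settings that merged peaks within 500 bp, kept the range every list reaches, used the names as in the files, kept only peaks inside the named gene, took equal top peaks or the shared range for gene lists over 3 days, took pairs of C and L lists as units or left out same-numbered pairs were chosen after the data were seen, and the others before. The lists hold no read counts, so what depth limits could not be measured. Of the settings on the main results other than omissions, 140 values kept direction and call, 38 moved without turning, 13 turned direction, 8 of them ratios of single lists that crossed 1, and 1 came to pass its test. After the omission of 1 list 51 were kept, 19 moved and 5 reversed. On gene lists, 120 were kept, 7 reversed and 33 came to pass the test, the last all with the synapse lists of 3 days taken as independent and 5 of them with equal top peaks. Merging at 100 bp, chromosomes 1 to 19, X and Y alone, names as in the files, and peaks inside the named gene alone changed no direction or call and moved no count by over 1.5 times. Transcript regions and the share of repeated CXX triplets, with their own alternatives, were not run, as no exon annotation or genome sequence was used here. The cause was not tested for any change below unless given.

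With the authors' -log10 p at least 10, the synapse L over C ratio on day 1 was 0.932 for peaks, below 1 where it had been above, and 0.909 for genes, and the gene ratio on day 20 was 1.00035, turned from below 1. With the authors' fold at least 5, homogenate L minus C was 369 peaks, reversed, and genes of C alone numbered 17. Genes of L over C were 1.03 on day 1 and 1.02 on day 20, above 1 where they had been below, and 0.988 on day 6, and peaks on day 6 were 1.17. The log2 difference over both fractions was 0.051, reversed, at an exact permutation p of 0.525. Genes of both controls alone were 516, of all homogenate lists alone 1131 and of both synapse lists alone 63, fewer or more because fewer peaks entered. The microglia list was 1.96 percentage points higher in synapse, reversed.

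Counted as covered bases, L over C was 0.536, 0.713 and 0.815 on days 1, 6 and 20, below 1 where peak counts were above, the day 6 value in part because the L list lacks the rest of the genome (0.842 in the shared range). With peaks within 500 bp merged, it was 1.02, 1.01 and 1.00018 and homogenate L minus C was 20 peaks, reversed. Counted as peaks shared at 1 bp in place of genes, homogenate L alone held 68 and C alone 79. Synapse L alone held 3920, 4426 and 3673 and C alone 3843, 4212 and 3603 on days 1, 6 and 20. Both cKO lists alone held 97 and both synapse lists alone 247. At a reciprocal overlap of 50%, these were 60 and 95, then 5888, 5695 and 4716 for L and 5422, 5281 and 4447 for C. Both cKO lists alone then held 14, all homogenate lists alone 1437 and both synapse lists alone 344.

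With equal numbers of top peaks, both controls alone held 129 genes, both cKO lists alone 170, all homogenate lists alone 640 and both synapse lists alone 263. With equal top peaks in the shared range over 3 days, synapse minus homogenate reversed to 8.08 percentage points for postsynaptic, 5.56 for presynaptic, 17.7 for ion channel, 11.4 for GABAergic, 1.33 for translation factor and 24.4 for microglia genes. This setting compares most of each synapse list with the top of each homogenate list, so these reversals do not by themselves show a gain in synapse. The 5 lower shares that passed are not due to shorter lists, but all genes were lower too, at 30.8% in homogenate and 24.6% in synapse. With the synapse lists of all 3 days, the gene ratio to homogenate was 0.394 and passed its test with all lists taken as independent, and 6 genes were in every synapse list alone. In the range every list reaches, L over C on day 6 was 1.26 for peaks and 1.07 for genes, the latter turned from below 1, with 663 genes in C alone, because the L list lacks the rest. The log2 difference over both fractions was then 0.025, reversed.

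Omitting 1 list at a time gave homogenate L minus C of -506 to 389 peaks and -169 to 364 genes, both crossing 0, and a similarity difference of -0.0405 to 0.000921. Genes of L alone ran from 78 to 153 and of C alone from 51 to 128. The log2 difference over both fractions ran from -0.047 to 0.0067, the highest without day 6 of the synapse. Genes of both controls alone ran from 1424 to 2053 and of both cKO lists alone from 51 to 400. The cKO peak ratio ran from 0.0881 to 0.394. Genes of all homogenate lists alone ran from 2272 to 2832 and of both synapse lists alone from 23 to 71, and the gene ratio from 0.356 to 0.397.

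With the replicate number as a block, homogenate L minus C was -169 peaks (exact sign-flip permutation p = 1) and 138 genes (exact p = 0.75), and the log2 difference over both fractions -0.02 (exact permutation p = 0.594). The cKO ratio was 0.187 (exact permutation p = 0.5), and the block changed no call among these. The peak, gene and cKO results could not have passed, as 3 pairs or fewer allow no exact sign-flip p under 0.25. The similarity within groups minus that of same-numbered lists was -0.0705, which holds the effect of the pairing, and minus that of lists of different number it was 0.00021, reversed, so the difference reported came from the pairing. With pairs of C and L lists as units, the synapse to homogenate gene ratio over 3 days, 0.394, had an exact permutation p of 0.10, so the call with all lists as independent ended, as did those on gene lists, because 3 units per fraction allow no smaller p. Same-numbered control and cKO lists correlated at 0.0384 in their deviations, so those numbers were not taken as a pairing of samples. The first and second pair of the cKO set match lists by the number in the label alone.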

Other observations

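The labels do not give the fraction of the cKO set, and its control lists were near the synapse lists in some gene groups and apart from them in others. Histone genes had a peak for 1.39% and 2.78% of members in the 2 control lists, and choroid plexus markers for 7.69% and 0%. Postsynaptic density and glutamate receptor genes stood at 66.7% and 71.4% there. Microglia and macrophage markers stood at 17.6% and 23.5%, against 41.2% to 47.1% in the synapse lists, and principal neuron markers at 34.8% and 39.1%, against 43.5% to 60.9%. Which fraction the control lists were nearer to depended on the measure, and each measure depends on list length. Of the genes of the first control list, a mean of 85.3% had a peak in the homogenate lists and 69.6% in the shorter synapse lists, and for the second 86.8% and 71.1%. With equal numbers of top-ranked peaks of the homogenate and synapse lists the means were 59.0% and 65.3% for the first and 59.4% and 66.3% for the second. The mean Jaccard index of the gene sets was 0.270 with homogenate and 0.466 with synapse lists for the first, and 0.298 and 0.513 for the second. Nat10 had a peak in 5 of the 6 homogenate lists and in no synapse list. In the C lists its peak with the highest fold, 7.57, lay inside the gene at chromosome 2, 103760902 to 103761227. In the L lists the highest, 11.8, was named after Nat10 and lay outside its span, at 103709249 to 103709448.

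Of the tests on the 3 patterns weighed here, those on the minimum length of the first cKO pair, on joining synapse peaks, on the top-ranked peaks for histone genes and on other splits of the lists were chosen after the values they use had been seen, and the other tests before.

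The cKO lists held fewer peaks than the control lists. A difference in minimum peak length does not account for the first pair, whose lists share 1 minimum and still gave a ratio of 0.424. Loss of short peaks could account for much of the drop in the second pair, since only 881 of the 5132 control peaks were at least 500 bp long. A length cutoff on the control peaks as called does not account for all of it, since these were 2.09 times as many as the 422 peaks of the cKO list. The median peak was 855 bp in that cKO list and 369 bp in its control list. How many control peaks the settings of the cKO list would give cannot be seen from this count. Other peak settings thus stay open for the second pair. Lower detection sensitivity of the cKO libraries may contribute, since genes with strong control peaks kept a peak more often than genes with weak ones, by 11.03 percentage points in the first pair, just over the 10 set beforehand, and 14.8 in the second. A partial loss of ac4C could leave the same gradient, as could any 2 lists, and the control lists were not compared in this way. A loss of ac4C in the knockout thus stays open as well and was not tested apart from sensitivity, because the lists hold no read counts.

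The synapse L lists held more peaks than the C lists on each day as deposited, though not on day 1 at the authors' -log10 p of at least 10, where the ratio was 0.932, and the peaks were shorter. If narrower peaks had split regions, joining peaks at most 500 bp apart could remove the excess, and it left 0.586 of the mean log2 ratio within the range every list reaches, between the bounds set for either reading. The log2 ratio went from 0.10 to 0.04 on day 1, from 0.33 to 0.25 on day 6 and from 0.06 to 0.001 on day 20. A difference between C and L cannot be told apart from the peak settings on these lists, since each day has 1 list per group and the minimum length was 200 bp in C and 125, 150 and 175 bp in L on days 1, 6 and 20.

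Histone genes had peaks in homogenate and hardly any in synapse lists. Shorter synapse lists do not account for it, since the 6413 top-ranked peaks of the homogenate lists still held many histone genes. These were a median of 52.8% of the 72 histone genes with a peak in any list. Peaks named after neighbouring genes do not account for it either, since peaks of any name overlapped at most 1.39% of the spans of 72 histone genes in a synapse list, against 72.2% to 90.3% in homogenate. Replication-dependent histone mRNAs lack a poly(A) tail, so a step that selects tailed RNA in some libraries could give this pattern, as could a low share of these mRNAs at synapses. Neither was tested, since the labels give 1 protocol and no batch. That protocol, as summarised above, names total RNA and a whole RNA kit, and no selection of tailed RNA. The homogenate lists also differed from all others in gene names, with 53 to 119 updated symbols per list against 0 to 6. The control lists, named like the synapse lists, had a peak at 1.39% and 2.78% of histone genes. A gene annotation that differed between the lists was not tested apart from a difference between fractions.

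Splits of 3 against 3 lists number 10, too few for a share under 0.05. The homogenate C and L groups gave 62 genes in every list of 1 group and none of the other, and the highest other split 264, with 8 of the 10 splits at 62 or more. The 264 came from the split that put both first replicates and the third L list together. The splits that kept same-numbered lists together gave more genes, which points to a structure of the lists by number, from the samples or from their processing. The 3 other splits that part every pair as the real one does gave 50, 61 and 82. For the similarity within minus between groups, 8 of 10 splits were as high as the real -0.0234, and the highest other was 0.0347, with the pairing left in. In the synapse, 9 of 10 splits gave as many genes as the real 58, and the highest other gave 123. The 3 other splits that part the lists of each day gave 40, 58 and 66.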
